A study of Mus musculus with 12 samples.

How the data were processed

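PolyA-selected RNA of 12 libraries was sequenced, 3 from each of 4 stable derivatives of the mouse pancreatic stellate line ImPSC-1: shCtrl, shKitl, Egfp_OE and Kitl_OE. Per the labels' protocols, cells grew in DMEM with serum and pyruvate, RNA was isolated with an RNeasy micro kit and libraries were made with the NEBNext Ultra II RNA kit. Groups and replicate numbers were taken from the sample titles. The descriptions carry a P number (14, 15 and 16 in shCtrl, 13, 14 and 15 in shKitl, 17, 18 and 19 in Egfp_OE, 18, 19 and 20 in Kitl_OE) whose meaning the labels do not give.

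The authors deposited a table of raw read counts per gene, made per the submitters' processing notes with STAR 2.5.2b and featureCounts from Subread 1.5.2 on GRCm38; these notes also list DESeq2. They deposited the same libraries as TPM values (counts divided by gene length and scaled to a fixed total), which by the values sum to the same total in each library over all entries including spike-ins; how gene length was set is not given in the sources used here. The strand setting of the counting and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart and genes with near-identical copies are uncertain. Both tables held 49763 entries, 92 of them ERCC spike-in RNAs, which were kept out of library sizes and tests. Gene names came from the tables; names and coordinates were matched to GENCODE M21 by ID, which held 49326 of the 49671 gene IDs.

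Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (15271 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 12 libraries, so that the groups share one estimate of the spread (biological coefficient of variation 0.292). The contrasts were shKitl minus shCtrl, Kitl_OE minus Egfp_OE, the difference of the latter and the former, and Egfp_OE minus shCtrl. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were computed from the fold change and its F value. CPM values are counts scaled by library size and TMM factor. The smallest two-sided p of an exact permutation test of 3 against 3 libraries is 0.1. Intervals of count ratios are exact 95% intervals, and a group without counts was set to a floor of 3 counts; both cover counting error only. With 24979742 to 33517686 counts in genes per library, counting error was small beside the spread between libraries for all but the lowest genes.

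Before the data were examined, the tests, the alternatives, 29 gene lists and the rule for named genes were fixed. The lists covered the KIT pathway, collagens, matrix glycoproteins, matrix remodelling, contractile genes, TGF-beta response, inflammatory cytokines, interferon response, antigen presentation, retinoid and lipid storage, progenitor and adventitial markers, DNA replication, mitosis, cholesterol synthesis, glycolysis and hypoxia, ER stress, p53 targets, ERK targets, Wnt and Hedgehog genes, growth factors, integrins and cadherins, markers of pancreatic epithelium, endothelium, blood and mast cells, Schwann cells, mesothelium and pericytes, mitochondrial transcripts and replication histones. Each was tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. Some genes belong to more than 1 list, for example Myh11, and stellate cells express many of the marker genes themselves.

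The rule named Kitl, Kit, Col1a1, Acta2, Pdgfra, Pdgfrb, Il6, Cxcl12 and Eng whatever their values. It added the 10 highest and 10 lowest log2 fold changes among genes past 0.05 with a mean CPM of at least 5 in the higher group, no overlap of the libraries and a symbol that is not a predicted gene model. It added up to 4 members of each list past 0.05 with the largest absolute change, 10 genes called in both comparisons in opposite directions and 6 in the same direction, and 5 of each sign for the control lines. Some were left out for length, and some items are withheld and not reported here. Collagen, antigen, mesothelial and other list members given beyond these were chosen after their values were seen.

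Alternatives were DESeq2 size factors in edgeR, library totals, DESeq2 1.42.0, limma-voom (limma 3.58.1), limma on log2(TPM + 1) and log2(TPM + 0.1), all genes with any count, a CPM of at least 5 in 3 libraries, an adjusted p of 0.01, an absolute log2 fold change of at least 1, the replicate number as a block, the P number as a covariate, only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were scaling by spike-in totals, the libraries whose P numbers occur in both groups, list counts without Egfp_OE replicate 2, and the named-gene rule applied to the DESeq2 calls of the knockdown, since edgeR called none. Adjusted p-values that DESeq2 did not give were left out of its counts. Figures were drawn with matplotlib 3.10.9.

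The tests were tested on simulated counts for the same 15271 genes, with library sizes and means from the data and 200 genes changed. The changed genes were drawn from those with a mean CPM of at least 5. Counts were drawn independently for each gene, so structure shared by several genes across libraries was not simulated and the rates may differ in the real data. For the overexpression design edgeR recovered 38% of genes changed 2-fold and 95% of those changed 4-fold with 4.32% false calls, and DESeq2 66% and 98% with 18.8%. For the difference edgeR recovered 7% and 74% with 5.81% false calls, and DESeq2 31% and 90% with 23.4%. For the control lines edgeR recovered 30% and 93% with 4.65% false calls, and DESeq2 50% and 98% with 19.6%. Transcript isoforms, vector sequences and Egfp reads were not analysed here.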

Results

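RNA sequencing counted transcripts in ImPSC-1, an immortalised line of mouse pancreatic stellate cells. Stellate cells are the mesenchymal cells of the pancreas that store retinoids when quiescent and deposit collagen when activated. Stable derivatives of the line made up 4 groups of 3 libraries: cells with a control hairpin (shCtrl), cells with a hairpin against Kitl (shKitl), cells carrying Egfp as the overexpression control (Egfp_OE) and cells overexpressing Kitl (Kitl_OE). Kitl encodes stem cell factor, the ligand of the receptor tyrosine kinase KIT. Reads counted in genes came to 28831163, 25917337 and 24979742 in shCtrl replicates 1, 2 and 3, and to 27807736, 26949812 and 26888748 in the shKitl replicates. They came to 33517686, 25617898 and 27854375 in the Egfp_OE replicates and to 26998384, 27766355 and 29953626 in the Kitl_OE replicates. ERCC spike-in RNA took 1.35% of the counts of Egfp_OE replicate 2 and between 0.446% and 0.684% in the other 11 libraries. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

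Kitl (ENSMUSG00000019966, a protein-coding gene on the plus strand of chromosome 10 at 100015630 to 100100416, GRCm38) was the targeted gene in both designs. In CPM, counts scaled to the size of each library, it stood at 73.5, 73.6 and 76.4 in the 3 shCtrl libraries and at 25.1, 25.5 and 30.3 in the 3 shKitl libraries. The means were 74.5 ± 1.65 and 27.0 ± 2.88 (SD, n = 3 each), so that shKitl cells held 36.2% of the control level, a log2 fold change of -1.46 (SE 0.258). In Egfp_OE cells Kitl stood at 72.5, 31.8 and 72.3 CPM and in Kitl_OE cells at 125, 114 and 128 CPM. Their means were 58.8 ± 23.4 and 123 ± 7.32 (SD, n = 3 each), a 2.08-fold difference (log2 1.06, SE 0.255, adjusted p = 0.00836) that came to 1.69-fold without Egfp_OE replicate 2. In both comparisons the 3 libraries of one group lay outside the range of the other, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. In edgeR's quasi-likelihood test the knockdown of Kitl had an adjusted p = 0.121 with all libraries, 0.0397 without shKitl replicate 3 and 0.000725 without Egfp_OE replicate 2; over its 25 alternatives the adjusted p ran from 0.000128 to 0.999. The overexpression of Kitl lost its call when libraries were scaled by spike-ins (log2 0.95, adjusted p = 0.242; range over its 25 alternatives 0.000854 to 0.242). Counts per gene do not separate introduced from endogenous Kitl transcripts. Kit, the receptor gene, had 0 to 2 counts per library and was too low to be tested, so that a difference in it was not detectable at this depth.

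**Figure D1:**
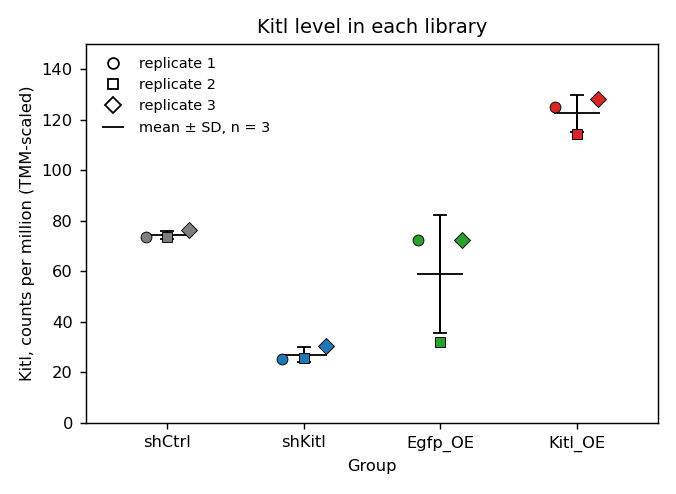
Kitl level in CPM in each of the 12 libraries, by group, with the mean and SD of 3 libraries; symbols mark the replicates. The shKitl libraries sit between 25.1 and 30.3, the Kitl_OE libraries between 114 and 128, and Egfp_OE replicate 2 sits at 31.8.

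The overexpression comparison asked how stellate cells with added Kitl differ from cells with added Egfp. Kitl_OE cells carried high levels of genes of mesothelium, the cell layer that lines the pancreas and other organs. Upk3b, a uroplakin gene used as a mesothelial marker (ENSMUSG00000042985, chromosome 5, 136038496 to 136046487), rose from 0.252 ± 0.169 to 147 ± 48.5 CPM (SD, n = 3; log2 9.23, SE 1.31, adjusted p = 0.00038). Gpm6a, a membrane glycoprotein gene of neurons and mesothelium (ENSMUSG00000031517, chromosome 8, 54954843 to 55060871), rose 871-fold from 0.185 ± 0.144 to 160 ± 45.1 CPM (log2 9.77, SE 1.00, adjusted p = 4.86e-05). All 6 measured mesothelial markers rose, Nkain4 by log2 8.64, Upk1b by 7.75, Bnc1 by 2.76 and Msln by 1.45, with a list median of 8.19 (7.19 without Egfp_OE replicate 3 and 7.49 without Kitl_OE replicate 2). The list held 12 genes. With all libraries Lrrn4, Muc16, Wt1, Krt5, Rspo1 and Calb2 were not among the genes kept by the count filter and were not tested. The filter asks for enough counts in 3 libraries, so a marker high in Kitl_OE cells alone was kept. The 6 left out did not reach that level in all 3 Kitl_OE libraries. The rise of all 6 measured markers therefore covers only the part of the list that was expressed. Dlk1, a membrane protein of fetal mesenchyme and preadipocytes (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), fell from 484 ± 188 to 2.16 ± 0.112 CPM (log2 -7.81, SE 0.321, adjusted p = 2.33e-07).

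By edgeR's quasi-likelihood test 5236 of 15271 tested genes (34.3%) passed an adjusted p of 0.05, 2352 of them higher and 2884 lower in Kitl_OE cells, and 1376 and 1932 of these differed by a log2 of at least 1. The groups did not overlap for 50.5% of the genes, where chance gives 10%. Beside Gpm6a, Upk3b and Nkain4, the strongest increases by the fixed rule were in Pkhd1l1 (log2 8.35), Prdm6, a transcriptional regulator of smooth muscle (8.17), and Mgll, the monoglyceride lipase gene (8.16). Tnfsf15, Xkr4, Lce3c and Ephx2 had 1 to 3 counts over the Egfp_OE group, and their ratios with 95% counting intervals were 518 (92.5 to 20500), 481 (164 to 2340), 371 (127 to 1800) and 353 (97.4 to 2920). Among the strongest decreases were Slc1a3, a glutamate transporter gene (-8.04), Gcnt4 (-7.76) and B4galnt4 (-7.71). Nudt11 and Kcnt2 had no count in Kitl_OE cells and were at least 165-fold and 159-fold lower, against a floor of 3 counts over the group. Abcc8, Bend5, Sytl4 and Grid1, with 1 count in the group, were lower by ratios of 860 (154 to 34000), 840 (150 to 33200), 561 (100 to 22200) and 479 (85.6 to 19000). These intervals and floors cover counting error only. DESeq2 called 6020 genes (2699 higher, 3321 lower). Scaled by spike-ins, 2351 genes passed (1061 higher, 1290 lower), and 3458 passed in the 4 libraries whose description numbers occur in both groups.

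Contractile genes rose together. Of 25 measured contractile and myofibroblast genes 19 rose and none fell (22 and 0 adjusted over the list alone; median log2 1.23; camera adjusted p = 1.42e-08, but adjusted p = 0.466 with an estimated correlation). Scaled by spike-ins, 11 rose. Acta2, the smooth muscle actin that marks activated stellate cells (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), rose from 148 ± 63.4 to 2765 ± 983 CPM (log2 4.23, SE 0.799, adjusted p = 0.00215). Actg2 rose by log2 4.86, Cnn1 (calponin) by 4.85 and Lmod1 by 3.66. Of 22 measured collagens 11 rose and 4 fell (12 and 4 adjusted over the list alone; 9 and 2 when scaled by spike-ins; median 1.28; camera adjusted p = 0.00466, adjusted p = 0.790 with an estimated correlation). Col1a1, the main fibrillar collagen chain (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), rose from 1830 ± 395 to 10550 ± 1270 CPM (log2 2.53, SE 0.463, adjusted p = 0.00178). The basement membrane chains Col4a5 (2.99), Col4a1 (2.55) and Col4a2 (2.26) rose with it, and Col6a3 (-2.15), Col4a6 (-1.98), Col7a1 (-1.08) and Col8a1 (-0.76) fell; Col6a3 did not pass without Egfp_OE replicate 1 (-1.42) or Kitl_OE replicate 2 (-2.01). Of 22 measured p53 targets 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.90; camera adjusted p = 0.000935, adjusted p = 0.790 with an estimated correlation). Scaled by spike-ins, 4 rose and none fell. Eda2r, a receptor gene of the TNF receptor family, rose by log2 2.27, and Plk2, a polo-like kinase gene, fell by 0.82. Cdkn1a, the cell cycle inhibitor p21, rose by 1.80 (adjusted p = 0.0176), a call that ended without Egfp_OE replicate 1 (log2 1.70) or replicate 3 (1.65). The mesothelial list had a camera adjusted p of 1.17e-05, its 6 members passed adjusted over the list alone, and it had an adjusted p = 0.4 with an estimated correlation.

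Of 41 measured interferon response genes 32 fell in Kitl_OE cells and none rose (35 and 0 adjusted over the list alone; median log2 -3.42; camera adjusted p = 6.35e-06, adjusted p = 0.790 with an estimated correlation). Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) fell from 109 ± 124 to 1.23 CPM (log2 -6.47, adjusted p = 0.00391), and Iigp1, a GTPase that acts against intracellular parasites, fell by log2 5.72, Zbp1, a sensor of nucleic acids, by 5.60 and Oas1a by 5.23. Of 18 antigen presentation genes 9 fell and none rose (11 and 0 adjusted over the list alone; median -1.61; camera adjusted p = 0.0337, adjusted p = 0.790 with an estimated correlation), led by H2-Q4 (-5.99), the immunoproteasome subunit Psmb8 (-5.56) and H2-K1 (-5.17). Within its group these genes were highest in Egfp_OE replicate 2, the library with the most spike-in reads and the lowest Kitl of its group: H2-K1 stood at 822 CPM there and at 88.0 and 53.2 CPM in Egfp_OE replicates 1 and 3. Without that library 20 interferon genes fell (median -2.17, camera adjusted p = 0.00213, adjusted p = 0.914 with an estimated correlation), 4 antigen presentation genes fell and 1 rose (median -0.47, camera adjusted p = 0.273), and Psmb8, at log2 -2.75, did not pass. The interferon count was 18 without Kitl_OE replicate 1 and 20 without replicate 3, and the antigen presentation count was 4, 4 and 5 without Kitl_OE replicates 1, 2 and 3, and 6 when scaled by spike-ins. Members of the H2-, Oas1, Ifit3, Gbp and Sprr2 families share sequence with close copies, and values of single members are uncertain.

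Another 5 lists passed camera downward. Of 25 measured cytokine and acute phase genes 11 fell and 3 rose (11 and 3 adjusted over the list alone; median -1.41; camera adjusted p = 0.0232, adjusted p = 0.790 with an estimated correlation). Without Egfp_OE replicate 2 the median was -0.60, with 9 lower and 3 higher. Il1rl1, the IL-33 receptor, fell from 174 to 2.23 CPM (log2 -6.28), the monocyte chemokine genes Ccl7 and Ccl2 fell by 3.89 and 3.71, and Lif rose by 2.58. Of 25 cholesterol synthesis genes 14 fell and none rose (14 and 0 adjusted over the list alone; median -0.69; camera adjusted p = 0.00109, adjusted p = 0.790 with an estimated correlation). Pmvk fell by 2.31. That count was 8 without Kitl_OE replicate 1, 7 without replicate 3 and 3 when scaled by spike-ins. Of 26 Wnt and Hedgehog genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.48; camera adjusted p = 0.0411, adjusted p = 0.790 with an estimated correlation). The counts were 8 and 0 when scaled by spike-ins, and the median was -1.08 without Kitl_OE replicate 3. The largest changes were Rspo2 (-6.14), Hhip (-6.12), Lef1 (-5.33) and Gas1 (-4.78), against Smo (1.07) and Wnt5a (0.94). The calls of both ended without Kitl_OE replicate 1 (1.08 and 0.98) or 3 (1.06 and 0.76). That of Smo also ended without Kitl_OE replicate 2 (1.12), and that of Wnt5a without shCtrl replicate 2 (0.96), Egfp_OE replicate 2 (0.70) or 3 (0.81). Of 9 pericyte and smooth muscle markers 5 fell, among them Rgs4 (-6.79), Anpep (-3.60) and Rgs5 (-3.54), and Myh11, smooth muscle myosin, rose by 3.92 (6 and 1 adjusted over the list alone; median -2.87, and -3.76 without Kitl_OE replicate 3; camera adjusted p = 0.0338, adjusted p = 0.790 with an estimated correlation). Of 7 measured pancreatic epithelial markers 4 fell and none rose (4 and 0 adjusted over the list alone; median -1.78; camera adjusted p = 0.000935, adjusted p = 0.4 with an estimated correlation). Among them were Spp1, the secreted phosphoprotein osteopontin (1797 to 42.8 CPM, log2 -5.39), Sox9, a transcription factor of ducts and cartilage (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760; -4.61), and the digestive enzyme gene Cela1 (-1.78). In all 11 of the 29 lists passed camera, none with an estimated correlation. By fry, which asks only whether the genes of a list move, on balance, one way, 10 passed. Interferon response, antigen presentation and collagens were not among these 10 (fry adjusted p = 0.0947, 0.152 and 0.0605). ERK targets and replication histones, which did not pass camera, passed fry (fry adjusted p = 0.0221 each).

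**Figure D2:**
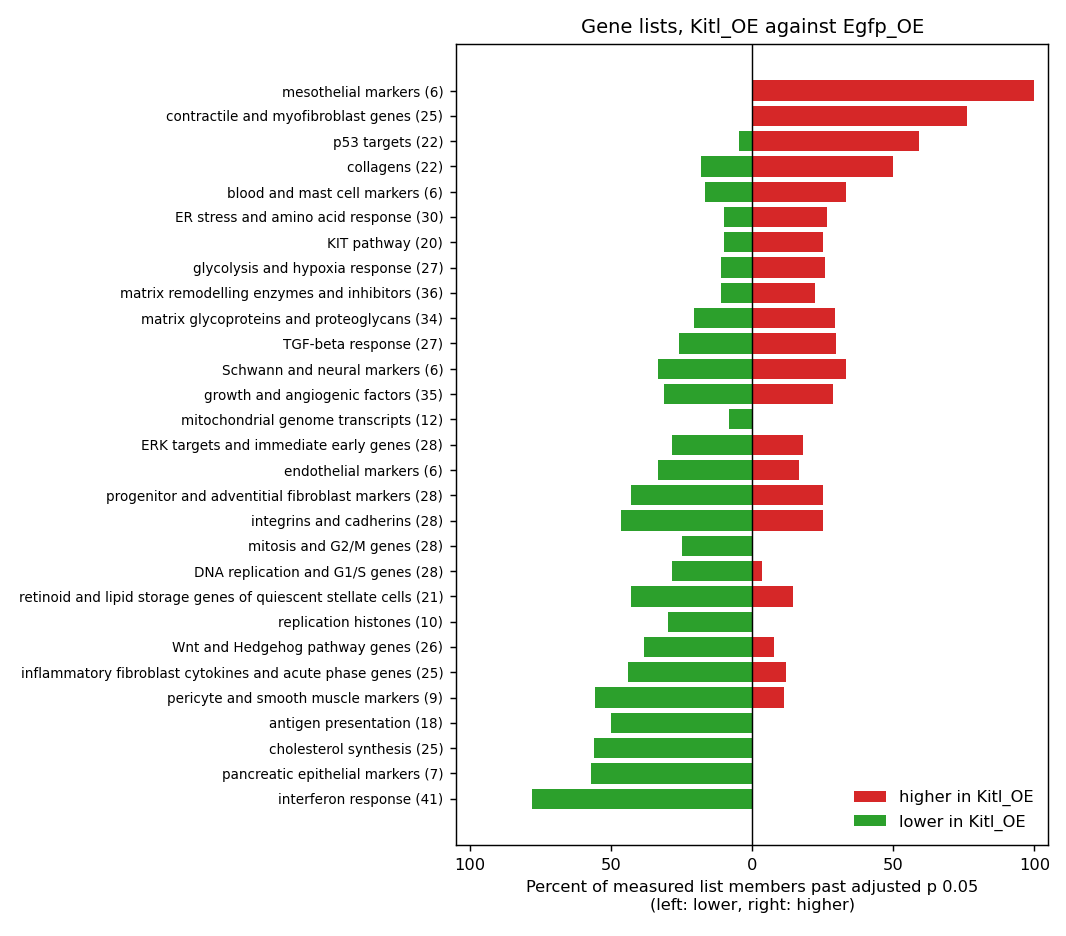
Percent of the measured members of each of the 29 gene lists (number measured in parentheses) that passed an adjusted p of 0.05 between Kitl_OE and Egfp_OE cells, lower to the left and higher to the right. All 6 measured of the 12 listed mesothelial markers were higher, and 32 of 41 interferon response genes were lower.

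Pdgfra, the PDGF receptor that marks fibroblasts (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), fell from 195 ± 36.2 to 15.2 ± 2.85 CPM (log2 -3.68, SE 0.529, adjusted p = 0.000412). Cd34, a marker of adventitial fibroblasts (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279), fell from 75.2 to 0.782 CPM (log2 -6.58, adjusted p = 4.02e-07). Eng, the TGF-beta coreceptor endoglin, rose from 90.5 ± 12.2 to 240.5 ± 6.66 CPM (log2 1.41, SE 0.201, adjusted p = 0.000396). Pdgfrb (log2 0.97, adjusted p = 0.0631), Cxcl12 (0.73, adjusted p = 0.154) and Il6 (-0.43, adjusted p = 0.574) did not pass, although Pdgfrb passed with DESeq2 (log2 0.97, adjusted p = 0.0342) and without shCtrl replicate 1 or 3 or shKitl replicate 2 or 3 (log2 0.97 to 0.99). Of 28 progenitor and adventitial markers 12 fell and 7 rose (12 and 10 adjusted over the list alone). Matrix glycoproteins gave 10 higher and 7 lower of 34 (11 and 8 adjusted over the list alone), with Fbln1, the fibulin of elastic matrix (ENSMUSG00000006369, chromosome 15, 85205949 to 85286535), down from 179 to 1.33 CPM (log2 -7.08), Thbs2 at -6.96 and Mfap2 at -6.20. Their median was 0.10, while their mean (-0.51) and the camera direction were negative. Retinoid and lipid storage genes gave 3 higher and 9 lower of 21 (3 and 9 adjusted over the list alone), with Crabp1 at -7.29 and Aldh1a1 at 6.30. With counts adjusted over the list alone in parentheses, the TGF-beta list gave 8 higher and 7 lower of 27 (9 and 7), with Ctgf at 3.41, Ltbp4 at 2.96 and Ltbp2 at -4.48, a median of 0.35 and a mean of -0.19. Tgfbi, among the lower, did not pass without Egfp_OE replicate 1 (-2.19) or Kitl_OE replicate 1 (-2.37) or 3 (-2.12). Matrix remodelling gave 8 and 4 of 36 (8 and 4), with Tgm2 at 4.72, Loxl1 at -3.78 and Timp3 at 2.47 (2.28 and not past the threshold when scaled by spike-ins). Integrins and cadherins gave 7 and 13 of 28 (8 and 14), with Cdh6 at -5.25 and Itga1 at 3.56. None of these 6 lists passed camera with all libraries. Without Egfp_OE replicate 2 integrins passed (adjusted p = 0.0463, but adjusted p = 0.872 with an estimated correlation). The retinoid list passed without Egfp_OE replicate 1 (0.0261) or 3 (0.0389), but not with an estimated correlation (adjusted p = 0.808 and 0.814 with an estimated correlation). Scaled by spike-ins, 5 remodelling genes rose and 2 fell, 4 TGF-beta genes rose and 5 fell, and 4 integrin and cadherin genes rose and 7 fell.

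For 12 further lists each pair of counts, higher and lower, is followed by that adjusted over the list alone. The KIT pathway list had 5 higher and 2 lower of 20 measured (5 and 4 adjusted over the list alone; 5 higher and 6 lower without Egfp_OE replicate 2), with the phosphatase gene Ptpn6 at log2 2.67, the kinase genes Lyn at 1.76 and Fyn at 1.18, and Pik3r1 at -1.08. Kitl itself, the targeted gene, is a member of this list and among the 5 higher, so the list is not a measure of pathway response alone. Growth and angiogenic factors gave 10 and 11 of 35 (11 and 11), with Bmp4 at 5.65, Angpt1 at -5.23 and Hgf at -4.23, and Igfbp2, with 3 counts in the Egfp_OE group, higher by a ratio of 216 (73.5 to 1050). ERK targets gave 5 and 8 of 28 (5 and 8), with Hmga2 at -2.70, Fosl1 at -1.91 and Dusp5 at -1.45. Dusp4, among the higher, did not pass without Kitl_OE replicate 2 (1.64) or 3 (1.51). ER stress genes gave 8 and 3 of 30 (9 and 4), but 14 and 4 without Egfp_OE replicate 2, with Gdf15 at 2.76 and Chac1 at 1.95. Glycolysis gave 7 and 3 of 27 (7 and 3), with Pfkfb3 at 1.76, a median of -0.16 and a mean of 0.10. Ldha, among the lower, did not pass without Kitl_OE replicate 1 (-0.88) or 2 (-0.91). Replication genes gave 1 and 8 of 28 (1 and 8), with Cdc6 at -1.41. Mitosis genes gave 0 and 7 of 28 (0 and 7), with Birc5 at -1.73, Ttk at -1.56 and Ccnb2 at -1.48. Ccna2, another of the lower, did not pass without Kitl_OE replicate 1 (-1.13) or 2 (-1.04). Replication histones gave 0 and 3 of 10 (0 and 6; median -1.71, and -1.03 without Egfp_OE replicate 1). Endothelial markers gave 1 and 2 of 6 (1 and 2), with Kdr at 2.69. Blood markers gave 2 and 1 of 6 (2 and 2), with Lyz2 at 4.44 and Gata2 at -3.51, a median of -0.64 and a mean of 0.18. Schwann cell markers gave 2 and 2 of 6 (2 and 2), with Erbb3 at 2.35. Mitochondrial transcripts gave 0 and 1 of 12 (0 and 1). Scaled by spike-ins, Pik3r1 (-1.15), Dusp5 (-1.42) and Cdc6 (-1.37) no longer passed. In that scaling the counts were 3 and 0 for the KIT pathway, 2 and 3 for ERK targets, 6 and 0 for ER stress, 2 and 0 for glycolysis, 0 and 0 for replication, 0 and 3 for mitosis, 0 and 2 for histones, 1 and 0 for endothelium and 0 and 0 for mitochondrial transcripts. None of these 12 lists passed camera with all libraries. Without Egfp_OE replicate 2, ER stress (adjusted p = 0.00197), mitosis (0.00977) and histone genes (0.026) passed, but not with an estimated correlation (adjusted p = 0.771, 0.914 and 0.887 with an estimated correlation). Mitosis passed without Kitl_OE replicate 3 (0.0213), histones without Egfp_OE replicate 3 (0.0368) or Kitl_OE replicate 1 (0.0348), and the KIT pathway without Egfp_OE replicate 3 (0.0417). These 4 had an adjusted p = 0.797, 0.770, 0.827 and 0.814 with an estimated correlation.

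**Figure D3:**
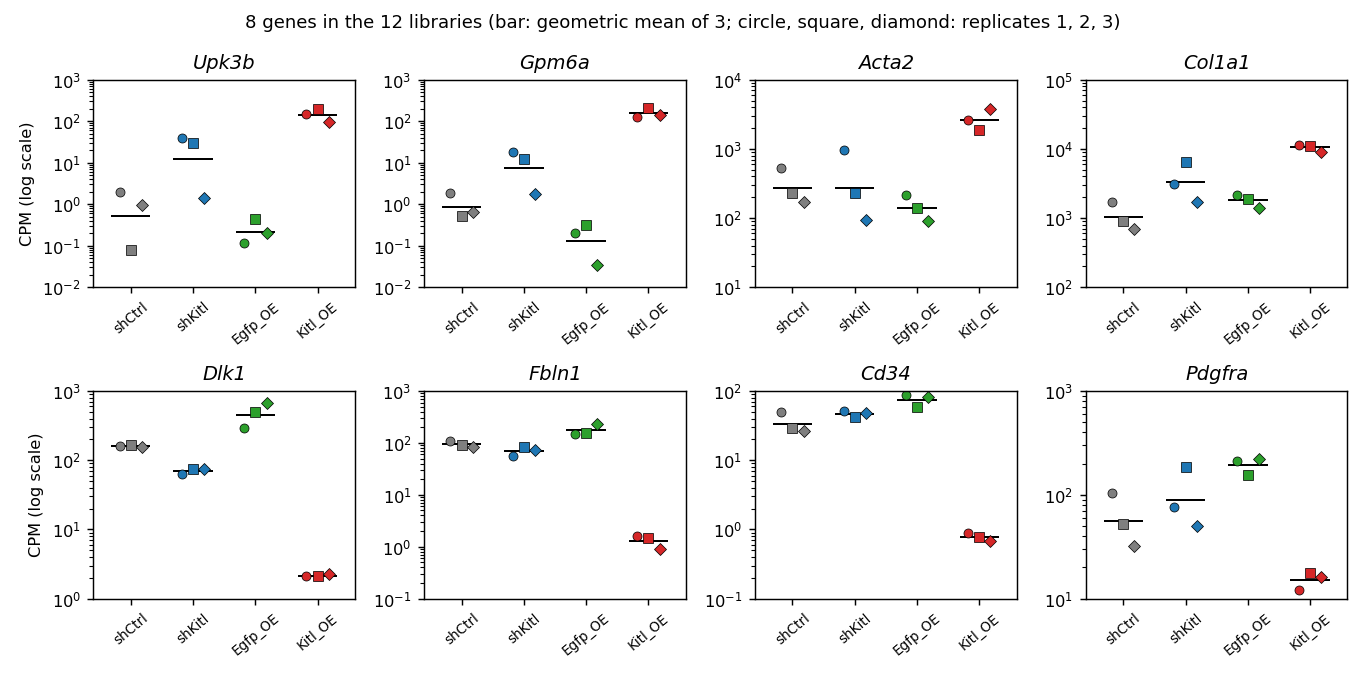
CPM, on a log scale, of 8 genes in each of the 12 libraries, by group; the bar is the geometric mean of 3 libraries and the symbols mark replicates 1, 2 and 3. Upk3b and Gpm6a were also above the control range in shKitl replicates 1 and 2, and Dlk1, Fbln1, Cd34 and Pdgfra were lowest in the Kitl_OE libraries.

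The knockdown comparison asked how stellate cells change when they lose part of their Kitl. All 41 measured interferon response genes had a positive log2 fold change in shKitl against shCtrl cells (median 1.91, and 3.16 without shCtrl replicate 1), but none passed, 0 adjusted over the list alone (camera adjusted p = 2.86e-20, adjusted p = 0.569 with an estimated correlation). For 35 of them all 3 shKitl libraries lay above all 3 shCtrl libraries. Isg15, a ubiquitin-like interferon-induced modifier, had 368 ± 36.0 against 107 ± 110 CPM, Ifit1 485 ± 42.8 against 122 ± 109 CPM and Bst2 (tetherin) 1049 ± 179 against 281 ± 256 CPM (SD, n = 3 each). The shCtrl libraries differed widely from each other in these genes, with interferon scores (mean log2 CPM relative to the 12 libraries) of 1.21, -0.56 and -1.95 against 1.62, 2.23 and 2.04 in shKitl. All 18 antigen presentation genes (median 1.76) and 24 of 25 cholesterol synthesis genes (median 0.60) were on the higher side, and all 28 mitosis genes on the lower side (median -0.41), with Mki67 at 281 against 498 CPM. No member of these 3 lists passed (16, 10 and 0 adjusted over the list alone; adjusted p = 0.481, 0.340 and 0.576 with an estimated correlation). The shKitl libraries lay wholly below the shCtrl libraries for 7 of the 28 mitosis genes, and the mitosis score of shKitl replicate 3 (0.34) lay within the shCtrl range (0.24 to 0.52).

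No single gene passed in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.121; 2417 genes had an unadjusted p under 0.05, 1701 higher and 716 lower. The limma-voom count was 0, limma on TPM values gave 0, and DESeq2 called 427 genes, 313 higher and 114 lower. On simulated knockdown data edgeR recovered 27% of genes changed 2-fold and 98% of those changed 4-fold with 4.58% false calls, and DESeq2 recovered 58% and 100% with 19.8% false calls. The simulated changed genes had a mean CPM of at least 5, and no structure of the samples was simulated. These rates therefore do not show that changes of such size would have been found in the real libraries. The groups did not overlap for 19.7% of the genes, where chance gives 10%. Leaving out shCtrl replicate 1, shKitl replicate 3 or Egfp_OE replicate 2 gave 82, 277 and 81 edgeR calls, and the other 9 omissions gave 0. Among the 5 genes of smallest p, chosen after their values were seen, were Gpt2 (log2 0.96), Rassf3 (-1.13), Ccdc43 (-1.18) and Efnb1 (-0.94). Col1a1 stood at 3807 ± 2489 against 1103 ± 530 CPM (SD, n = 3; log2 1.79, adjusted p = 0.182; it passed without shKitl replicate 3, log2 2.12). Acta2 had log2 0.46 (adjusted p = 0.785), Pdgfra 0.73 (0.462), Pdgfrb 0.91 (0.282), Cxcl12 0.74 (0.354), Il6 0.05 (0.975) and Eng 0.51 (0.268; it passed without shKitl replicate 3, log2 0.71).

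Genes called by DESeq2 in shKitl cells, by the same fixed rule, were higher for the carboxypeptidase gene Cpz (DESeq2 log2 4.82, adjusted p = 0.000627), Gabra3 (3.66), Oas1g (3.58), Gbp4 (3.32), Sprr2b (3.21), Ptprq (3.01), Myom2 (2.97), Sh3tc1 (2.88), Anxa8 (2.83) and Sprr2a3 (2.79). They were lower for the neuronal pentraxin gene Nptx1 (-3.51, adjusted p = 0.000497), the imprinted noncoding RNA Rian (-2.39), the urea transporter gene Slc14a1 (-2.33), the transcription factor gene Foxc2 (-1.92), Npnt (-1.85), Mfap3l (-1.83), Gcnt4 (-1.78), the prostaglandin receptor gene Ptger4 (-1.65) and Mb21d2 (-1.62). Its calls among the lists included Upk3b (4.52), Gpm6a (3.39) and Bnc1 (1.91) of the mesothelial markers, Cd74 (2.85) and Tap2 (2.01) of antigen presentation, Mvd (0.88) and Hmgcs1 (0.60) of cholesterol synthesis, and Col1a1 (1.74), Col4a5 (1.28) and Col1a2 (1.14) of the collagens.

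Of the 29 lists 14 passed camera in the knockdown comparison, 11 up and 3 down, although edgeR called no member of any. Those up with each of the 12 libraries left out in turn were interferon response (adjusted p = 2.86e-20), antigen presentation (2.63e-12), cholesterol synthesis (3.78e-09), collagens (median 0.63, 0.000135) and mesothelial markers (median 2.95, and 3.67 without shCtrl replicate 1; 0.000165); mitosis was down in all of them (3.73e-08). With an estimated correlation no list passed: adjusted p = 0.569 with an estimated correlation for interferon, 0.481 for antigen presentation and mesothelial markers, 0.340 for cholesterol synthesis and 0.576 for collagens and mitosis. Adjusted over the list alone, 0 interferon, 16 antigen presentation, 10 cholesterol, 4 collagen, 5 mesothelial and 0 mitosis genes passed. The mesothelial score was 1.23 and 1.18 in shKitl replicates 1 and 2 and -1.10 in replicate 3, against -0.84 to -1.69 in shCtrl. Another 8 lists passed with all libraries and lost the call without 1 of them: matrix remodelling (median 0.56; 0.0649 without shKitl replicate 2), growth factors (0.61; highest 0.167 without shKitl replicate 2, and also lost without shKitl replicate 1, shCtrl replicate 3, Egfp_OE replicate 1 or 2), Wnt and Hedgehog genes (0.71; 0.268 without shKitl replicate 2 and 0.124 without shCtrl replicate 3), progenitor markers (0.49; 0.179 and 0.114 without the same libraries), p53 targets (0.41; 0.0827 and 0.084 without shKitl replicates 1 and 2), ER stress (0.21; 0.322 without shKitl replicate 3 and 0.059 without shCtrl replicate 1), and, downward, replication genes (-0.18; 0.0649 without shKitl replicate 2) and ERK targets (-0.07; 0.111 without shKitl replicate 3). For these 8 lists the value was adjusted p = 0.576 with an estimated correlation, except 0.340 for ERK targets. Contractile genes had a median of -0.21 and did not pass (camera adjusted p = 0.0751), but passed downward without Egfp_OE replicate 2, shCtrl replicate 2 or 3 or shKitl replicate 1 (adjusted p = 0.0388, 0.0472, 0.0296 and 8.58e-05). With an estimated correlation they did not (adjusted p = 0.67, 0.645, 0.637 and 0.461 with an estimated correlation).

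**Figure D4:**
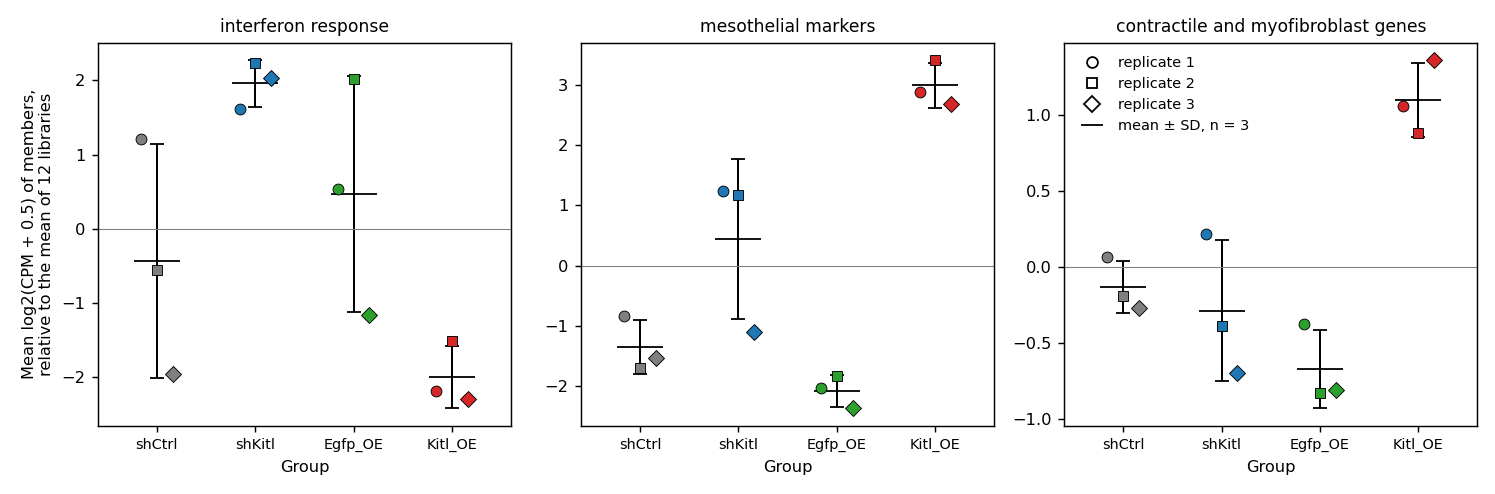
Mean log2(CPM + 0.5) of the members of 3 gene lists in each library, relative to the mean of the 12 libraries, by group, with mean and SD of 3 libraries. Interferon response scores were 1.62 to 2.23 in shKitl and -2.29 to -1.51 in Kitl_OE libraries; Egfp_OE replicate 2 scored 2.02.

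The opposite manipulations raised the question whether genes follow the Kitl level both ways. The difference of the responses does not answer this alone, since a gene changed in only 1 comparison can pass. Acta2, on the higher side in both comparisons, was such a case. Tested as a difference of the overexpression and knockdown responses, 2131 genes passed, 622 with the more positive and 1509 with the more negative response to overexpression (DESeq2 2929, 1019 and 1910; 162 and 757 when scaled by spike-ins). Kitl differed by log2 2.52 (SE 0.363, adjusted p = 0.0011), Acta2 by 3.77 (SE 1.02, adjusted p = 0.0314) and Pdgfra by -4.41 (SE 0.702, adjusted p = 0.00206), while Eng (0.90, adjusted p = 0.0526), Col1a1 (0.74, adjusted p = 0.466), Il6 (-0.48, adjusted p = 0.72), Pdgfrb (0.06, adjusted p = 0.957) and Cxcl12 (-0.01, adjusted p = 0.99) did not pass. Of 41 interferon response genes 35 differed, all with the more negative response to overexpression (41 adjusted over the list alone; median -5.20; camera adjusted p = 4.43e-19, adjusted p = 0.504 with an estimated correlation). That count was 19, 19, 19 and 23 without Kitl_OE replicate 1, Kitl_OE replicate 3, shCtrl replicate 2 and shKitl replicate 2. The median was -4.105 without Egfp_OE replicate 2 and -6.36 without shCtrl replicate 1. Contractile genes differed the other way in 16 of 25 (21 adjusted over the list alone; median 1.28; camera adjusted p = 9.27e-12, adjusted p = 0.217 with an estimated correlation), with 6 to 10 members without Egfp_OE replicate 3, Kitl_OE replicate 1 or 3, shCtrl replicate 2, or shKitl replicate 2 or 3, and 9 when scaled by spike-ins. Cholesterol synthesis differed downward in 11 of 25 (24 adjusted over the list alone; median -1.07; camera adjusted p = 1.69e-09, adjusted p = 0.217 with an estimated correlation), with 19 without Egfp_OE replicate 2, 17 without shCtrl replicate 1 and 2 when scaled by spike-ins. Lowest and highest counts of all genes with 1 library left out were 1245 without Kitl_OE replicate 1 and 2842 without Egfp_OE replicate 2, and 1263, 1366 and 1385 passed without shCtrl replicate 2 and Kitl_OE replicates 2 and 3.

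No gene passed edgeR's test in both comparisons, since the knockdown had no call. Among DESeq2 calls 60 genes went in opposite directions and 224 in the same direction, with no control library shared. Of the former, 48 were higher after knockdown and lower after overexpression (62.7 for independent lists, one-sided Fisher's exact p across genes 0.987) and 12 the reverse (19.5, p = 0.982). Of the latter, 175 were higher in both (53.4 for independent lists, exact p = 8.29e-56) and 49 lower in both (22.8, exact p = 1.94e-08); genes are not independent replicates. The shared direction was uneven between libraries. Of the 5236 genes edgeR called in the overexpression comparison, 71.89%, 61.52% and 52.25% lay on the same side in shKitl replicates 1, 2 and 3. That share fell as the P number rose, so a common response to both manipulations cannot be told from structure of the samples. Opposite by DESeq2, after knockdown and overexpression in turn, were Oas1g (3.58 and -4.65), Gria4 (2.47 and -6.08), Gbp4, Sprr2b and Sprr2a3, and, in the other orientation, Kitl, the Ras-association gene Rassf3 (-1.17 and 1.90), the ephrin gene Efnb1 (-0.98 and 1.05), the ERK feedback inhibitor gene Spry4 (-0.84 and 0.75) and the AMPK subunit gene Prkab2 (-0.70 and 0.79). In the same direction were Upk3b (4.52 and 9.21), Cpz (4.82 and 6.30), Igf2 (4.05 and 3.96), Nptx1 (-3.51 and -6.58), Meg3 (-2.59 and -6.58) and Grid1. Of the opposite genes, Gbp4 and Sprr2a3 lost their edgeR call in overexpression without Egfp_OE replicate 2 (-2.66 and -2.35) or any single Kitl_OE replicate. Scaled by spike-ins, Kitl, Gbp4, Efnb1, Spry4 and Prkab2 lost theirs. With limma on log2(TPM + 1), Gbp4, Sprr2a3, Gria4, Spry4 and Prkab2 did not pass in overexpression. With 1 library left out edgeR gave 14 opposite genes without Egfp_OE replicate 2, 15 without shKitl replicate 3, 21 without shCtrl replicate 1 and 0 without any other.

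**Figure D5:**
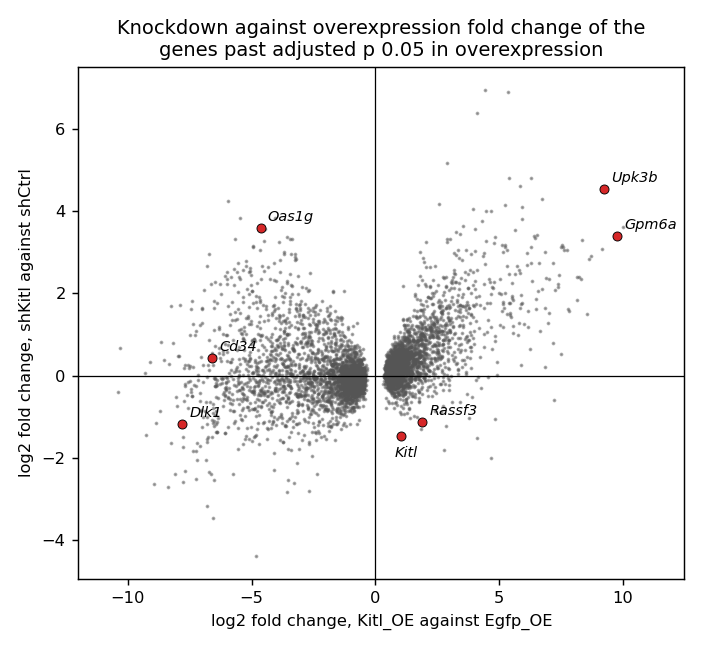
Each point is 1 of the 5236 genes past an adjusted p of 0.05 between Kitl_OE and Egfp_OE cells; the horizontal axis is that log2 fold change and the vertical axis the log2 fold change of shKitl against shCtrl. Of the 2352 genes higher in Kitl_OE cells 78.3% were also on the higher side after knockdown, and of the 2884 lower ones 57.3% on the lower side, where 54.4% of all genes were on the higher side.

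The control lines, Egfp_OE against shCtrl, gave the background between derivatives of ImPSC-1 with no Kitl construct. Their constructs differ and their P numbers do not overlap, so construct, P number and line cannot be told apart here. Egfp_OE cells were higher in Olig1, a neural transcription factor gene (27.9 ± 18.2 against 2.23 ± 1.01 CPM, SD, n = 3; log2 3.63, adjusted p = 0.0434), the growth factor gene Ptn (log2 3.13), Igfbp3 (3.12), Zdbf2 (2.83) and Sv2c (2.70). They were lower in the transcription factor gene Sox13 (-4.10, adjusted p = 0.0096), Ripor2 (-3.72), Galntl6 (-3.42) and BC030500 (-3.40). With the replicate number as a block in edgeR's test, Olig1, Ptn and Igfbp3 did not pass (adjusted p = 0.0595, 0.0556 and 0.0521). All 25 cholesterol synthesis genes were on the higher side, with 2 called (17 adjusted over the list alone; median 0.70; camera adjusted p = 1.19e-09, adjusted p = 0.480 with an estimated correlation). That count of 2 was 8 without Egfp_OE replicate 2 or shCtrl replicate 1, 1 without shKitl replicate 1 or 2, and 0 without Egfp_OE replicate 3, shCtrl replicate 2 or 3, or any Kitl_OE library, and 0 when scaled by spike-ins. Interferon response genes were up as a list (median 1.00, no member called, 0 adjusted over the list alone; camera adjusted p = 0.00991, adjusted p = 0.941 with an estimated correlation). They had a median of -0.06 and an adjusted p of 0.95 without Egfp_OE replicate 2, an adjusted p of 0.498 without shCtrl replicate 3, and a median of 2.25 without shCtrl replicate 1. Contractile genes (median -0.58, adjusted p = 0.00532), mitosis genes (-0.32, adjusted p = 0.00532; 0.179 without Egfp_OE replicate 2) and mesothelial markers (-2.14, adjusted p = 0.0102; 0.0673, 0.109 and 0.135 without Egfp_OE replicate 1, Egfp_OE replicate 3 and shCtrl replicate 1, the last with a median of -1.10) were down as lists. In these 3 lists 0, 0 and 1 genes passed (3, 0 and 1 adjusted over the list alone), and the values were adjusted p = 0.895, 0.941 and 0.895 with an estimated correlation.

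In the controls 191 genes passed, 78 higher and 113 lower, against 1461 by DESeq2, and 3721 had an unadjusted p under 0.05. The groups did not overlap for 28.5% of the genes, where chance gives 10%. This count rested on single libraries: it was 0 without Egfp_OE replicate 3, 2 without shCtrl replicate 2, 2 without shCtrl replicate 3, 461 without Egfp_OE replicate 1, 336 without Egfp_OE replicate 2 and 771 without shCtrl replicate 1, and lay between 44 and 127 without a Kitl_OE library or shKitl replicate 1 or 2. Scaled by spike-ins, which moved the median of all genes from 0.05 to -0.34, 0 genes were higher and 10 lower, and the medians of 14 lists changed sign. This scaling lowers Egfp_OE replicate 2 the most, with 1.35% spike-in reads against 0.586% and 0.565% in Egfp_OE replicates 1 and 3. Of the 5 lists called here the interferon median went from 1.00 to 0.05, that of cholesterol synthesis from 0.70 to 0.27, and those of contractile, mitosis and mesothelial genes to -0.90, -0.63 and -2.77. Kitl itself had log2 -0.34 (adjusted p = 0.414) between the control lines.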

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

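The tests of scaling, of a response that follows Kitl, of a cell population and of a swapped library were chosen only after the result was seen; the test of gene length and the other splits of the samples were not.

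The responses to overexpression and to knockdown differed by their own test in 3 of the fixed genes: Kitl by log2 2.52 (SE 0.363, adjusted p = 0.0011), Acta2 by 3.77 (SE 1.02, adjusted p = 0.0314) and Pdgfra by -4.41 (SE 0.702, adjusted p = 0.00206). In data outside the comparisons, spike-in reads took 1.35% of Egfp_OE replicate 2, against at most 0.684% in any other library.

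The pattern most worth following is the distance between the Kitl and Egfp overexpression lines, 5236 genes for a 2.08-fold difference in Kitl. All 6 measured of the 12 listed mesothelial markers were up. A scaling error would put nearly all calls on one side, but with spike-in scaling the smaller side still held 45.1% of the calls. A response that follows Kitl both ways would reverse in the knockdown, yet only 33.3% of these genes had the opposite sign there (28.1%, 38.5% and 47.8% in shKitl replicates 1, 2 and 3). That share rose with the P number of these libraries. In the knockdown edgeR called no gene, while a split of the same libraries by P number called 1665. The signs may therefore reflect structure other than the hairpin, so they cannot decide. A cell population at a larger share in the Kitl_OE cultures may still account for part of the distance between the lines. In shKitl replicates 1, 2 and 3, 94 genes high in Kitl_OE and chosen to be low in Egfp_OE stood at medians of 27.1%, 14.9% and 3.46% of the Kitl_OE level. In shCtrl replicates 1, 2 and 3 they stood at 8.45%, 2.97% and 1.93%, so that only shKitl replicates 1 and 2 lay above all shCtrl libraries. Inside both groups the share fell as the P number rose. Between shKitl and shCtrl libraries of equal P number it was 14.9% against 8.45% (P14) and 3.46% against 2.97% (P15). Hairpin and P number cannot be told apart here. In the tighter of shKitl replicates 1 and 2 the span between the lower and upper quartile was 1.27 log2 units, wide for 1 share though not enough to exclude such a population. An effect of Kitl itself, and differences between lines that arose in their making, stay open and untested, since the labels name no second line per construct.

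The other pattern is Egfp_OE replicate 2, which stood apart from its group with Kitl at 31.8 CPM, Bst2 at 2784 against 308 and 121 CPM, and Med12 at 6.37 against 94.8 and 96.7 CPM. A library of the shKitl line under the wrong label would lie at 1 on the line from Egfp_OE to shKitl, but over 666 genes that differ between these groups its median position was 0.19 (quartiles -0.11 and 0.60). Its log2 ratio to replicates 1 and 3 fell with gene length (Spearman rho -0.47 across genes, which are not independent replicates; 0.04 between replicates 1 and 3, though -0.29 in shKitl replicate 1 and 0.18 in shKitl replicate 2 against their groups), which is consistent with lower RNA input or RNA decay, as is the spike-in share. Whether the high interferon genes of this library have the same source stays open. Without it 6150 genes passed in the overexpression comparison and 4616 of the 5236 kept their call and direction.

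Splits of the same 6 libraries into 3 and 3 are 10 with the real one, too few for a share under 0.05. The knockdown count was 0 and the highest other 1665, from the split of shCtrl replicate 1 and shKitl replicates 1 and 2 against the rest, so all 10 splits gave as many genes. That split parts P numbers up to 14 from those of 15 and above and points to a structure of the samples beside the hairpin. The overexpression count was 5236 and the highest other 0, so 1 of 10 splits gave as many, and for the controls the count was 191 and the highest other 53, again 1 of 10. The lists past the threshold numbered 14 in the knockdown (highest other 17; 3 of 10 splits) and 11 in the overexpression comparison (highest other 13; 2 of 10). For the difference, 6 of 100 drawn splits, the real one included, gave at least the 2131 genes, with 5248 as the highest other, so chance was not excluded; all 6 were among the 14 that kept the overexpression labels, and the highest with those labels moved was 0. For genes in opposite directions the count was 0, the highest other 857, and all 100 splits gave as many.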

How the results depend on the processing

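Spike-in scaling, the libraries with shared P numbers and the DESeq2-named genes were chosen after the result was seen. The other alternatives were planned. Spike-in scaling weighs most on Egfp_OE replicate 2, the library with 1.35% spike-in reads. Over 181 named results and 3074 alternatives, 2854 kept direction and side of the threshold, 148 lost the threshold, 64 gained it and 8 reversed; the cause was not tested. In the knockdown, DESeq2 called 427 genes and the test on genes with any count 23, and omissions of 1 library gave 0 to 277. In the overexpression comparison the count was 2351 with spike-in scaling, 3458 in libraries with shared P numbers, 2822 at an adjusted p of 0.01, 3308 at a log2 of at least 1, and 3501 to 6150 with 1 library left out. None of its 5236 genes reversed under any setting, and 2289 kept their call with spike-in scaling. The difference gave 1105 and 1127 genes with limma on log2(TPM + 1) and log2(TPM + 0.1), 919 with spike-in scaling, 818 at 0.01, and 1245 to 2842 with 1 library left out; library totals moved its median of all genes from -0.09 to -0.19 and spike-ins to 0.10, and spike-ins moved that of the knockdown from 0.05 to -0.06. The controls gave 1461 with DESeq2, 307 with limma-voom, 89 and 38 with limma on TPM, 349 for genes with any count, 10 with spike-in scaling, 1 at 0.01, 0 with the P number as a covariate, 0 with only the 2 groups compared, and 0 to 771 with 1 library left out. Opposite genes numbered 60 with DESeq2, 4 for genes with any count, and 0 to 21 with 1 library left out.

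Kitl passed in the knockdown with DESeq2 (log2 -1.50) and for genes with any count (-1.47), with a range of -1.57 to -1.42 when 1 library was left out; in the overexpression comparison it was lost with spike-in scaling (0.95) and ran from 0.77 to 1.24 with 1 library left out. Acta2 in the knockdown reversed to -0.028 with limma on log2(TPM + 1) and ran from -0.94 to 1.09 with 1 library left out. Il6, with at most 3.42 CPM in a library, reversed to -0.039 in the knockdown with spike-in scaling and ran from -0.17 to 0.33 there, and from -1.01 to 0.22 in the overexpression comparison, with 1 library left out. Lists past the threshold in the knockdown numbered 0 with an estimated correlation, 1 with fry (cholesterol synthesis, fry adjusted p = 0.0323) and 9 to 16 with 1 library left out. In the overexpression comparison they numbered 0 with an estimated correlation and 11 to 14 with 1 library left out. Low counts limit Kit, which could not be tested.

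The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.15, -0.26 and 0.53 in the knockdown and at 0.03, 0.20 and 0.17 in the overexpression comparison. Libraries with the same P number correlated at 0.56 (shCtrl replicate 1 and shKitl replicate 2) and 0.32 (shCtrl replicate 2 and shKitl replicate 3) in the knockdown, and at -0.002 and -0.18 in the overexpression comparison. With the replicate block the counts were 0 for the knockdown, 5186 for overexpression, 2118 for the difference and 82 for the controls, and the lists numbered 14 and 12.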

Other observations

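The genes below and the interferon tests were chosen only after the result was seen. Dlk1, Meg3 and Rian, which lie in 1 imprinted cluster, had lower values after both manipulations; the cluster was not tested as a list, and edgeR called none of them in the knockdown. Dlk1 stood at 161, 167 and 156 CPM in the shCtrl libraries and at 62.5, 75.2 and 74.6 CPM in the shKitl libraries (DESeq2 log2 -1.23, adjusted p = 0.00152; not called by edgeR), and fell by log2 7.81 in Kitl_OE cells. Of the noncoding RNAs, Meg3 had -2.59 (DESeq2 adjusted p = 0.0049) after knockdown and -6.53 (edgeR adjusted p = 0.000142) after overexpression, and Rian -2.39 (DESeq2 adjusted p = 0.000201) and -6.73 (edgeR adjusted p = 2.73e-05). Of the other imprinted pair, Igf2 was higher in both (DESeq2 4.05 after knockdown, edgeR 3.95 after overexpression), while H19 fell by 7.45 in Kitl_OE cells (edgeR adjusted p = 0.00219), where Egfp_OE replicate 2 alone held 74.2 CPM against 4.92 and 5.67 in replicates 1 and 3.

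The interferon response score was high in shKitl and low in Kitl_OE libraries, by 2.40 in the knockdown and -2.46 in the overexpression comparison. The size of the latter rests in part on Egfp_OE replicate 2, which scored 2.02 against 0.54 and -1.16 in Egfp_OE replicates 1 and 3. The score of shCtrl replicate 3 (-1.95) lay inside the range of the Kitl_OE libraries (-2.29 to -1.51). The exact two-sided permutation p of the difference of differences (-4.86) was 0.005, the smallest that the 400 labellings can give, consistent with, as a hypothesis, an effect of the Kitl manipulation, but the list was picked from 29 after its values were seen. The P number of the description as the whole cause would leave no gap between libraries of equal P number. The gaps of the 4 such pairs were 1.02 (P14) and 2.59 (P15) in the knockdown, and -4.20 (P18) and -0.35 (P19) in the overexpression comparison. Signed to the manipulation, their mean was 2.04 (SD 1.72, n = 4), and 1.32 (SD 1.15, n = 3) without Egfp_OE replicate 2. All 4 gaps had the sign of the group difference, but their sign carries no information on the P number. The compared groups did not overlap in this score, so any pair of libraries would give that sign. Each gap sets 1 library against 1, and the gaps spread too widely to decide. Whether the P number is part or all of the cause cannot be told apart. The pooled slope within groups was -0.57 per P (exact two-sided permutation p = 0.193 over 1296 permutations). By group the slopes were -1.58, 0.21, -0.85 and -0.06 in shCtrl, shKitl, Egfp_OE and Kitl_OE. Differences between lines that arose in their making stay open and untested, and the score spread widely inside shCtrl (1.21 to -1.95) and Egfp_OE (2.02 to -1.16).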
